A study of Mus musculus with 2 samples.

How the data were processed

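The series measured 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine made by the TET enzymes, across the genome of R1 mouse embryonic stem cells. R1 is an established XY embryonic stem cell line. Per the labels' protocols, the cells were kept in 2i medium, then formed embryoid bodies in suspension under atmospheric oxygen, and were taken at day 3 of differentiation. DNA of 3 samples was pooled, sheared to fragments of 200 to 1000 bp, and 1 µg was enriched with a polyclonal 5hmC antibody (hydroxymethylated DNA immunoprecipitation, hMeDIP). Sequencing libraries were made from 2.5 ng of the enriched DNA and of total genomic DNA as the input control, with 200 bp inserts, 12 PCR cycles and single reads of 50 cycles on a MiSeq, a low-throughput instrument. The design therefore holds 2 libraries, 1 per group, and the pooling leaves no replicate spread to measure. The input library is the only control, and no library made with a non-specific antibody was analysed here.

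The file used here is a list of enriched regions that the authors made by comparing the enriched library with the input. Bowtie and MACS 1.0.1 are named in the submitters' processing notes, without their roles, and BaseSpace and Galaxy are named in the labels' protocols. The settings of the peak calling, and the tool that annotated the regions, are not given in the sources used here. Each region was deposited with a peak score, 1 value per region, whose scale neither the file header nor the labels name; it is used to rank regions within the list and to set thresholds on it, some at multiples of the lowest score, and a multiple of the score is not a fold of signal. A fold enrichment had been planned as the measure of strength, and the score took its place. Regions were deposited as windows of 51 bp, all of the same size, so the width of the enriched segment is unknown. The CpG and GC columns were deposited under a percent sign but hold a fraction, in steps of 1 of 50 dinucleotides and 1 of 51 bases; they describe the reference sequence in the window, not its modification. Matches to 15 sequence motifs, listed per window by the authors, were used only as present or absent. No read counts or library sizes were used here, so the depth behind each region is unknown.

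Builds were checked before coordinates were used. The submitters' processing notes name mm9, but the coordinates in the file are those of GRCm38 (mm10). A transcription start was computed for each region from its position and its deposited distance, and set against a RefSeq gene table of GRCm38.p6. Of 661 regions whose nearest gene was in that table on the same chromosome, 317 gave a start within 5 bp of an end of the gene and 529 within 1 kb. Of 233 intron regions with a matched transcript, 230 lay within the GRCm38 bounds of its gene. All coordinates below are GRCm38 as the file gives them. A negative distance was read as upstream of the start, since 163 of the 174 regions in an intron of their own nearest gene had a positive distance. Nearest genes were matched by gene identifier, and 667 of 668 regions had a match. The gene that holds a region was taken from the transcript named in its annotation, which the table held for 245 of 253 such regions.

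Location, repeat and nearest gene are those of the authors' annotation. The share of regions in genes was also computed from the gene table by the window midpoint and set against 100 random placements of the windows on the same chromosomes. Chromosome lengths were not used here, so placements and densities per Mb cover the span from the first to the last gene with a curated transcript. CpG observed over expected is the number of CpG in a group's windows divided by the number its GC content gives for bases in random order. Genome sequence was not used here, so shares of repeats and CpG have no genomic background beside them. In advance, 26 lists of genes, 627 genes in all, and 4 gene families were fixed. Lists of cell states were core and naive pluripotency, primed epiblast, primitive streak and mesoderm, endoderm, neuroectoderm, trophectoderm and germ cells. Lists of gene regulation were imprinted genes, Hox clusters, DNA methylation and demethylation, histone demethylases and related proteins, and Polycomb. Lists of metabolism and signalling were hypoxia, glycolysis, oxidative stress, and the Wnt, TGF-beta, FGF and Notch/Hedgehog pathways. The other lists were adult neuron, liver, blood, muscle and fibroblast markers, and housekeeping genes. The families were olfactory and vomeronasal receptors, ribosomal proteins, Zfp zinc finger genes and protocadherins. For each list, the number of members that are the nearest gene of a region was set against 10000 random lists of the same size, matched on gene length in 10 classes, from 26220 genes with curated transcripts or a region. These shares describe the 2 libraries, since genes are not replicates, and a Benjamini-Hochberg adjusted share over all 30 lists is given beside the raw one. With 1 library per group, no p-value across replicates was computed, and the shares of random lists take genes as their units. Simulated listings over the same 26220 genes used lists of 30 genes. Lists with 5 times the background rate of listing fell in the top 0.05 in 66.5% of 200 draws. Lists with 10 times the rate did so in 99.5%, and unchanged lists in 3.5%. These draws used the raw share, so they do not give the sensitivity of the adjusted share or of smaller lists. Shares of regions carry exact (Clopper-Pearson) 95% intervals, which cover counting error only.

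The genes named are the 20 regions with the highest score, the 10 genes with the most regions (ties broken by score), every listed member of the core, naive and primed pluripotency, DNA methylation and imprinted lists, and up to 4 members of each other list, except for some genes that are not reported here. Genes outside this rule are said to have been chosen after their values were seen. The alternatives were stricter score thresholds, merging within 1 kb, other definitions of location, other backgrounds and matching for the lists, and several subsets of the regions. Matching of the gene lists was looked at in 3 ways: on gene length, which is the main result, and without matching, both set before the data were examined, and on the distance between neighbouring genes, which was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.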

Results

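The data compare DNA enriched with an antibody against 5hmC with total input DNA from the same kind of cells, R1 mouse embryonic stem cells at day 3 of differentiation as embryoid bodies under atmospheric oxygen. Each group is 1 library from DNA of 3 pooled samples, so no value below has a replicate error, and intervals cover counting error only. The authors' list holds 668 enriched regions, nearest to 610 genes. The number of reads behind a region is unknown. The question of the comparison was where in the genome 5hmC lies in these cells.

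The enriched regions lay mainly in tandem repeats. Repeats of the dinucleotides CA or TG held 295 of the 668 regions (44.2%, 95% interval 40.4 to 48.0). A satellite annotated as IMPB_01 held 92 regions (13.8%), other simple repeats 84 (12.6%), and telomere-type TTAGGG or CCCTAA repeats 14 (2.10%). Together, simple repeats, satellites and low-complexity sequence held 517 regions (77.4%, 95% interval 74.0 to 80.5). Long terminal repeats of the ERVK class of endogenous retroviruses held 35 regions (5.24%), of which 11 were RLTR17B_Mm and 11 RLTR20A4. The remaining 107 regions (16.0%) had no annotated repeat. The share of each repeat in the genome was not computed, so these shares do not show enrichment over the genome. The sequence AC or GT in alternation was also found in several of these classes: the deposited motif ACACACACACAC matched 533 windows (79.8%), ACACACACAC 505 and GTGTGTGT 481, and at least 1 of these 3 motifs was present in 89 of the 92 IMPB_01 windows, 30 of the 35 ERVK windows and 79 of the 107 windows without a repeat. Motif matches allow mismatches, and 209 windows had a match with 10 uninterrupted bases of alternating CA or TG.

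**Figure D1:**
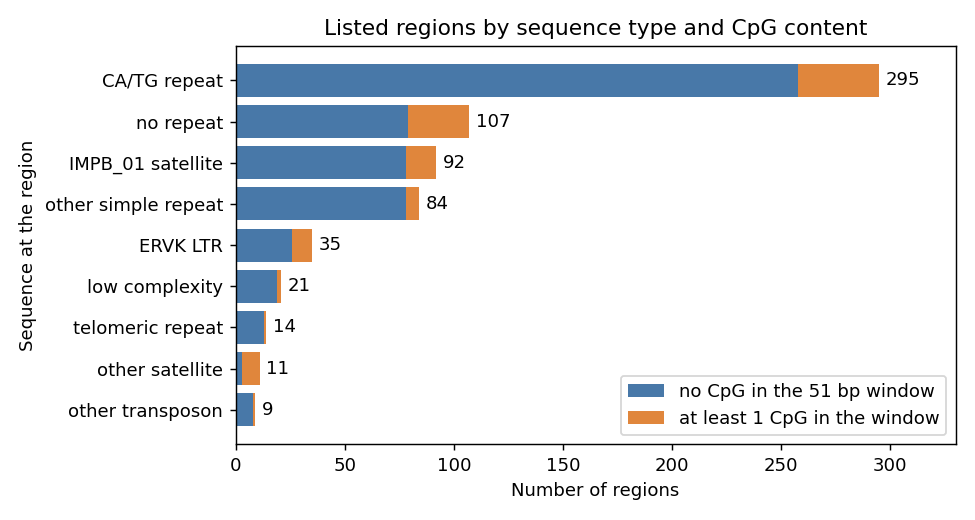
Number of listed regions (x axis) in each type of sequence (y axis), split by whether the 51 bp window of the reference holds a CpG, with the total at each bar. CA/TG repeats lead with 295 regions, and 258 of these have no CpG in the window.

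Most windows contained no CpG, the dinucleotide at which most cytosine methylation and hydroxymethylation of mammalian DNA occurs. At least 1 CpG was present in 106 of 668 windows (15.9%, 95% interval 13.2 to 18.9), and 562 had none. The number of CpG was 0.0888 of that given by the windows' GC content. Mammalian genomes are themselves poor in CpG, and no genome value was computed for comparison. The share with a CpG was 12.5% in CA/TG repeats (37 of 295), 15.2% in IMPB_01 (14 of 92), 25.7% in ERVK repeats (9 of 35) and 26.2% outside repeats (28 of 107). Satellites other than IMPB_01, mostly the major satellite GSAT_MM of pericentromeric heterochromatin, stood apart with 8 of 11 windows (72.7%, 95% interval 39.0 to 94.0). Windows without a repeat and without a CA/TG motif numbered 28, and 9 of these held a CpG. Those 9, chosen here after their values were seen, were the strongest region of the list at the Tet3 promoter, 3 regions upstream of Gata4, the Pgk1 promoter, introns of Eif3h and Nol9, and intergenic sequence nearest to Rn4.5s and Dynll2.

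The regions were mostly distant from promoters. The authors' annotation placed 415 regions (62.1%) between genes, 241 (36.1%) in introns, 7 (1.05%) at promoters and 5 (0.749%) at transcript ends. Only 9 regions (1.35%, 95% interval 0.618 to 2.54) lay within 1 kb of a transcription start and 59 (8.83%) within 5 kb. The median distance to the nearest start was 36.1 kb, and 171 regions (25.6%) were more than 100 kb away. Random placements were not set against the distances to a start, so these values do not show that regions avoid promoters. By the gene table, 269 regions (40.3%, 95% interval 36.5 to 44.1) lay in a gene, within the range of 39.7% to 47.6% of 100 random placements, whose mean was 43.0%. The annotated promoter regions other than the strongest one were at Slfn4 (score 6.35), Unc93b1 (5.22), Pgk1 (4.95), 2010009K17Rik (4.04), Olfr1200 (3.65) and Cabp2 (2.96), a set chosen after its values were seen.

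Peak scores took few values. They ran from 2.00 to 142 with a median of 4.95 and quartiles of 4.04 and 6.35, and 117 regions shared the score 4.95. Of 58 distinct scores, the 8 most frequent covered 528 regions (79.0%). The median score was 4.95 in CA/TG repeats, in IMPB_01 and outside repeats alike, and 21 regions scored 10 or more. CA/TG repeats, 44.2% of all regions, were 2 of these 21.

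**Figure D2:**
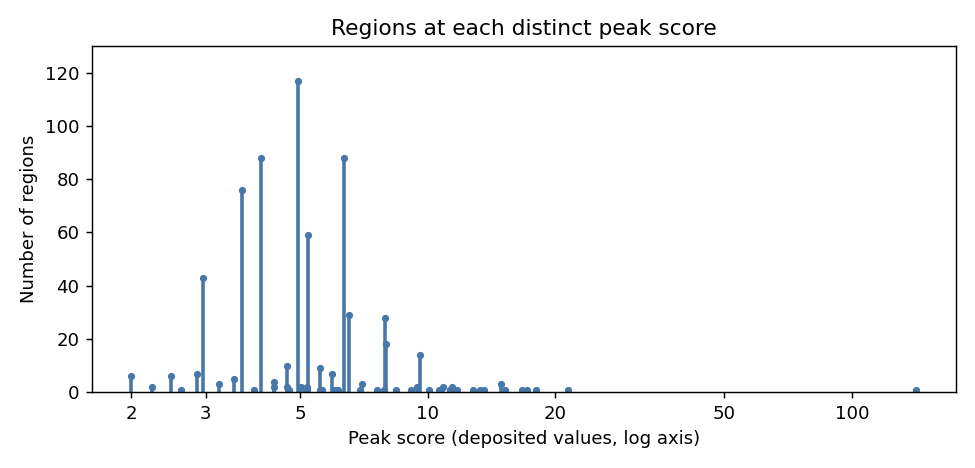
Number of regions (y axis) at each of the 58 distinct peak scores as deposited (x axis, log scale). Most regions share a few scores between 2.96 and 7.92, with 117 regions at 4.95, and a single region stands at 142.

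The highest score was 142 and the next 21.4. This region (GRCm38 chromosome 6, 83441876 to 83441926) was annotated as the promoter of Tet3, which encodes an enzyme that makes 5hmC, and its nearest start was that of the noncoding RNA gene B230319C09Rik, 146 bp away. The window was 60.8% GC with 3 CpG and no repeat. Overlapping genes of this kind cannot be told apart by position. Of the 20 highest-scoring regions, 14 lay in simple repeats or satellites, 6 held a CpG, and this was the only region within 1 kb of a start. Scores of 21.4 and 17.2 were those of regions in CTGTG repeats, in intron 1 of the noncoding RNA gene 2700054A10Rik. A region without a repeat 5.80 kb upstream of BC018473 scored 18.0. CA repeats 123 kb from 1700028D13Rik scored 16.7, and TG repeats 33.4 kb from Gm4791 scored 10.9. Major satellite sequence scored 15.2 in intron 1 of Mdga2, a neuronal adhesion gene, and 11.7 at 82.3 kb from Vmn1r2. TTAGGG repeats scored 13.6 at 98.0 kb from Lphn2 and 12.8 at 21.7 kb from Gm14496. Other simple repeats scored 14.9 at 87.2 kb from Apob and at 28.9 kb from Gm15319, and 13.3 at 99.7 kb from Gm4736. They scored 11.4 in intron 6 of Lvrn (nearest start 4833403I15Rik) and 10.9 at 8.36 kb from Pla2g4d. Regions outside repeats scored 14.9 in intron 10 of Rere (nearest start Slc45a1) and 11.4 in intron 26 of Ankrd27 (nearest start Pdcd5). Another scored 10.6 at 16.2 kb from Erdr1 on Y. An RLTR17B_Mm element in intron 11 of Nrap, a striated muscle gene, scored 11.3, and an IMPB_01 window 26.9 kb from the start of Erdr1 scored 11.3.

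Of the 610 genes, 44 had 2 or more regions and 11 had 3 or more. The highest number, 4 regions, was reached by 2700054A10Rik within 2.29 kb, by Mir205 over 137 kb and by Tbx5 over 154 kb. The Tbx5 regions were all IMPB_01 satellite, 52.2 to 90.5 kb from the start of this cardiac and limb transcription factor gene, with scores of 3.65 to 9.60. Gata4, a transcription factor gene of endoderm and heart, had 3 regions within 1.86 kb (chromosome 14, 63246484 to 63248348), at 1249, 2592 and 3063 bp upstream of its start. The Gata4 regions scored 6.35, 2.96 and 4.95, lay in no repeat and held 2, 3 and 3 CpG. Pisd-ps1 also had 3 regions with a CpG each, all in satellites, within 1.29 kb. Other genes with many regions included Erdr1, Gm4791, Psmd7 and Sipa1l2, with 3 each. Regions were more grouped than random placements: 95 lay within 100 kb of another region, against 20 to 54 in 100 placements. These 95 include several windows of the same locus, as at 2700054A10Rik, Gata4 and Pisd-ps1, which were not merged, whereas windows were placed independently.

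Pluripotency genes had 1 listed member in the core list and 1 in the naive list. Of 16 core pluripotency genes, the member was Tcf7l1 (score 4.95, CATA repeat, 31.6 kb upstream), a repressor in the Wnt pathway. Of 20 naive pluripotency genes, it was Prdm14 (6.35, TG repeat, 64.4 kb from the start), a regulator of naive pluripotency and germ cells. None of 14 primed epiblast genes was listed. These counts compare with 0.302, 0.504 and 0.382 members on average in random lists matched on gene length, and 0.261 and 0.404 of these held as many as the core and naive lists. No member was listed of the Hox clusters (0 of 39), trophectoderm (0 of 14), adult blood (0 of 20) and adult muscle (0 of 20). The same held for the list of histone demethylases and related proteins (0 of 24). Random lists of these sizes held 0.324 to 0.878 members on average.

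Germ cell genes had the most listed members for their number, 3 of 16 against 0.416 on average, and 0.0073 of the random lists held as many. The Benjamini-Hochberg adjusted share over the 30 lists was 0.219, so this list did not stand apart after adjustment. Among windows outside repeats it had 1 listed member (share 0.0629, random mean 0.0648). Its members were Prdm1 (scores 6.54 and 3.65), Prdm14, which is also in the naive list, and Mael (5.22, in a CA repeat in an intron of the gene). The mesoderm, endoderm and neuroectoderm lists had 1 or 2 listed members each. Tbx5 and Isl1 (7.99, CCCTAA repeat, 567 kb from the start) were listed of 26 primitive streak and mesoderm genes. Gata4 was listed of 20 endoderm genes and Irx3 (6.35, CA repeat, 9.08 kb upstream) of 25 neuroectoderm genes. The share of random lists with as many members was 0.0898, 0.444 and 0.444 in the same order. Fibroblast genes had 2 of 15 listed, Vim (6.54, IMPB_01) and Lum (2.86, GA repeat), with a share of 0.0512. Adult neuron genes had 2 of 30 (Rbfox1, 7.99, and Nlgn1, 6.35) with a share of 0.5001, and adult liver genes 1 of 20 (Apob), with 0.351.

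Among genes of DNA methylation and demethylation, Mbd2, which encodes a methyl-CpG binding protein, was the only one of 29 listed by nearest start. Its region (score 6.35) was an IMPB_01 window with 4 CpG in an intron of the gene, 41.0 kb from the start, and 0.527 of random lists held as many members. Tet3 enters the list when the gene that holds the region is counted. Of 39 imprinted genes, Plagl1 (5.57, RLTR20A4 element, 10.9 kb upstream) and Gnas (4.04, CA repeat with 1 CpG, 5.50 kb from the start, in an intron of its antisense gene Gnasas1) were listed, and 0.284 of random lists held as many. The Polycomb list had 2 of 29 members listed, among them Phf19 (6.54), hypoxia Arnt (4.95) of 29, oxidative stress Nqo1 (6.35) of 25, and glycolysis Pfkp (9.60, 550 kb upstream) and Pgk1 (4.95) of 17. The Pgk1 window, 110 bp upstream of the start of this glycolytic gene, held 3 CpG; Pgk1 was also the only listed one of 20 housekeeping genes. Signalling lists had Tcf7l1, Fzd5 and Tcf7l2 of 43 Wnt genes, Smad2, Tgfb2 and Tgfbr2 of 39 TGF-beta family genes, Fgf12 of 32 FGF genes and Notch1 of 28 Notch and Hedgehog genes. The share of random lists with as many was between 0.0579 and 0.628 for these lists, housekeeping included. Across the 26 lists, 29 genes had 35 regions, of which 30 lay in repeats, 6 held a CpG and 5 were within 5 kb of the start.

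Of 1486 olfactory and vomeronasal receptor genes, 7 were listed, against 17.9 on average in random lists of the same gene lengths, and 0.0016 of these held as few (adjusted 0.048). These genes sit in clusters and are not independent. The adjusted share was 0.216 by the gene that holds the region and 0.435 at no less than 2 times the lowest score. The low count did not hold after adjustment under these settings. With matching on the distance between genes the adjusted share was 0.051, hardly apart from 0.048, so the result lies at the limit. The listed ones include Vmn1r2 (2 regions, 11.7 and 9.13, major satellite), Vmn2r87 (8.43, TTAGGG repeat), Olfr1 (5.22) and Olfr30 (4.95). Zfp zinc finger genes (8 of 403, among them Zfp365 and Zfp369 at 6.54), ribosomal protein genes (Rpl38 and Rps29, 4.04 each, of 105) and protocadherins (Pcdhgc4, 4.04, of 70) did not stand apart, since 0.407, 0.768 and 0.25 of random lists, in that order, held as few. Median scores were 4.95 for the receptors and 4.61 for the Zfp genes, at the 42.4th and 24.7th percentile of random sets of listed genes.

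The regions were spread over all autosomes and nearly absent from X. Autosomes held 662 regions, or 0.274 per Mb, from 0.140 on chromosome 14 to 0.436 on chromosome 8 and 0.423 on chromosome 5. Chromosome X held 2 regions where 46.7 would match the autosomal density, a ratio of 0.0428 (exact 95% interval 0.00518 to 0.155). The 2 regions were the Pgk1 promoter and a window without a repeat 192 kb from Gm10921 (score 5.57), a gene named after its values were seen. None of the 295 CA/TG regions was on X, where 20.8 would match the autosomes, which allows a ratio of up to 0.178. Both X regions lay outside repeats, where 7.26 would match the autosomes and the ratio was 0.275 (exact 95% interval 0.0329 to 1.02). In repeats, X had no region against 39.4, which allows a ratio of up to 0.0939. The density of these repeats on X was not computed, so the ratios for repeats do not show less signal per repeat on X. Chromosome Y held 4 regions by the deposited coordinates, 3 of them at Erdr1. Sequence shared by X and Y was not examined, so a region there could not be assigned to either.

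**Figure D3:**
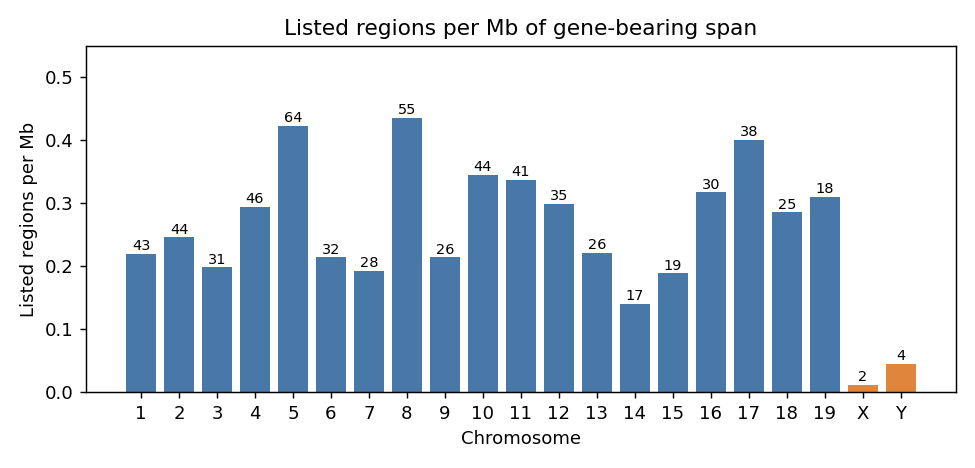
Listed regions per Mb (y axis) on each chromosome (x axis), with the number of regions above each bar; autosomes are blue and the sex chromosomes orange. Chromosome X, with 2 regions, lies at 0.0117 per Mb, below the lowest autosome at 0.140.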

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

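The subsets by CpG, by repeat and without the highest-scoring region, the use of the gene that holds the region, and the matching on distance between genes were chosen after seeing the data. The number of regions fell from 668 to 411 at or above the median score, 106 with a CpG and 107 outside repeats, and the number of genes from 610 to 381, 99 and 103 in the same order. Requiring 2 regions per gene left 44 genes, and requiring the region to lie in the gene or within 5 kb of its start left 204. The share within 1 kb of a start, 1.35%, was 8.83% within 5 kb, 3.77% with a CpG and 6.54% outside repeats. The ratio of X to autosomes, 0.0428, was 0.275 outside repeats, where X kept both of its regions, and stayed between 0.0429 and 0.138 under the other settings. The share of regions in genes stayed between 39.3% and 43.4% under all settings run. Lists in the top 0.05 of random lists numbered 1, and 2 without matching on length, 2 with genes of 2 or more regions, 2 at no less than 2 times the lowest score, 2 with matching on the distance between genes, 2 with the gene that holds the region, 3 at or above the median score, and 0 with only CpG windows or only windows outside repeats. The lists that entered were primitive streak and mesoderm, glycolysis and fibroblast genes, each with 1 or 2 listed members, where a single gene decides the call. The germ cell list had no member among CpG windows (share of random lists with as many, 1), where random lists held 0.0685 on average, so no direction can be read there, and 1 member outside repeats (0.0629, random mean 0.0648). For the receptor genes the share of random lists with as few, 0.0016, rose to 0.6916 with genes of 2 or more regions, 0.3026 with CpG windows and 0.2743 outside repeats, where random lists held 1.12, 2.32 and 3.62 members on average and a low count could hardly show. With more members expected, the share was 0.0145 at no less than 2 times the lowest score (6 against 13.5), 0.0184 at or above the median score (4 against 10.2), 0.0072 by the gene that holds the region, 0.0017 with matching on the distance between genes and 0.0018 without the highest-scoring region. Adjusted over the lists these were 0.435, 0.552, 0.216, 0.051 and 0.054, against 0.048 as reported and 0.003 without matching on length. The values 0.048, 0.051 and 0.054 are hardly apart and lie about the limit of 0.05. The adjusted result did not hold at the stricter score thresholds or by the gene that holds the region. A limit on the false discovery rate and a second measure of strength were planned and not run, since the list used here gives neither, and the planned fold threshold was applied to the score. Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each group has 1 library. With the depth unknown, a gene or chromosome without a region cannot be called free of 5hmC.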

Other observations

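All tests here, and the genes named, were chosen after the results were seen. ERVK elements among the stronger regions included a RMER17D2 copy 65.7 kb upstream of Sntg1 (score 9.60), a RLTR20A4 copy 142 kb from 1810053B23Rik (9.60) and the RLTR17B_Mm copy in Nrap, and 9 of the 35 ERVK windows held a CpG. The 14 TTAGGG or CCCTAA windows had a median score of 5.07, against 4.95 for all regions, and 1 of them held a CpG. In 61 of 245 regions inside a gene, the nearest start was that of another gene, as for Rere and Ankrd27.

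Enriched windows were mostly CA/TG and other tandem repeats, and a CpG beside the windows was not searched for, since genome sequence was not used here. Large segments present in extra copies stay open: 6.78% of CA/TG regions (20) lay within 100 kb of another, the highest number in random placements (mean 7.93, range 0 to 20), and over all regions 95 did, against a mean of 38.6 and a range of 20 to 54. For antibody binding to the repeat itself, a first test set the median score of CA/TG windows without a CpG against that of non-repeat windows with a CpG. It found a difference of 0 (4.95 in both), and could hardly have shown any, since scores took few values. Only 9 of the 28 non-repeat windows with a CpG had no CA/TG motif, so most of the comparison set held similar sequence. This first test was replaced, once seen, by the share of tandem or low-complexity sequence among regions scoring 10 or more. The share was 71.4% (15 of 21, 95% interval 47.8 to 88.7) against 77.6% of the rest. Windows annotated as CA or TG repeats were 9.52% of the former (2 of 21, 1.17 to 30.4) and 45.3% of the latter. Repeats of similar sequence, such as CTGTG and GTGTG, were counted apart, and motif matches were not counted by score. The lower share therefore covers the annotated CA and TG repeats only. None of these values decides, because 5hmC at or near the repeats was not told apart from binding to them by any library analysed here, and no biological explanation was tested.

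Chromosome X held 2 regions, both outside repeats. R1 cells have a single X, and the input library comes from the same kind of cells. A loss in proportion to copy number was taken to give a ratio near 0.5. The upper bound was 0.0939 for regions in repeats, under this value, and 1.02 outside repeats. These bounds do not decide, since the enriched and input libraries share the single X. How its copy number changes the count of called regions is therefore unknown. A single copy may also bring X regions under the threshold of the list: if only regions at 2, 3 or 4 times the lowest score stayed listed, 36.1, 14.7 or 2.61 would be expected on X, against an upper bound of 7.25 for the observed count, so that 2 and 3 times would leave too many and 4 times would not. This stays open because the scale of the score, and so the multiple that 1 copy would make, is unknown. Lower 5hmC on X was not tested.

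The region at the Tet3 promoter scored 142. The number of CpG within its window does not by itself account for this, since the other 7 windows with at least 3 CpG scored 7.92 at most. CpG in the rest of the enriched fragments, which are longer than the windows, was not counted. The CpG content of the locus therefore stays open. A DNA product of this one locus carried into the enriched library, such as an amplified fragment, might give a single sharp region. There was 1 other region within 1 Mb, in Dysf, and without read positions or a second enriched library this explanation cannot be told apart from focal 5hmC at the promoter. No biological explanation was tested.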
